A study of Mus musculus with 13 samples.

How the data were processed

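Polyadenylated RNA of mouse morulae, ICM and TE, from embryos cultured with or without nicotine, was made into 13 Smart-seq2 libraries, amplified over 16 to 18 PCR cycles and sequenced as paired-end reads of 150 bp on an Illumina HiSeq X-Ten or NovaSeq 6000. The labels do not say which library ran on which instrument or received which dose, so neither entered the models. The authors deposited a table of FPKM values, a unit already scaled by each library's size and by transcript length. The submitters' processing notes name STAR, StringTie 2.1.4, featureCounts 1.6.2, DESeq2 1.30.1 and the mm10 build, without their roles.

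The table held 29547 lines, of which 1990 repeated another line and were removed (219 identifiers), leaving 27557 genes, 27480 of them with a symbol. Gene positions, lengths and overlaps were taken from GENCODE M21 on the same build by gene identifier, with positions counted from 1; the annotation used by the submitters is not stated. Whether read counts can be recovered was checked over 78 pairs of libraries (667 to 2243 genes each): the fullest window of 0.02 on the log2 scale of their ratios held 0.96 to 2.09% of genes, and the median was 1.14%. No depth was inferred and no counting error is given.

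Libraries were grouped by stage and treatment as labelled. Genes with at least 1 FPKM in at least 2 libraries were tested (11386 genes). Values were transformed as log2(FPKM + 1) and fitted in limma 3.58.1 (R 4.3.3, data.table version 1.17.8) with 1 mean for each of the 6 groups over all 13 libraries, 7 residual degrees of freedom and empirical Bayes with an intensity trend (7.124 prior degrees of freedom). Tests were two-sided, adjusted by Benjamini and Hochberg over all tested genes and called at an adjusted p under 0.05. The comparisons were nicotine against control in each stage and averaged over the 3 stages, ICM against TE in control and in nicotine embryos, and the 3 differences of nicotine effects between stages. Group values are the mean FPKM ± SD over libraries, with n = 3 for nicotine morulae and n = 2 for every other group. When 1 library of a group of 2 is left out, the lone sample is assumed to vary like the other groups.

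A set of 32 gene lists was written for this tissue and treatment before the data were examined, as were the comparisons, the tests of genes and lists and most alternatives. Lists with at least 5 tested members (30) were tested with camera at a preset correlation of 0.01, adjusted over the lists within a comparison, and again with an estimated correlation and with fry; list changes are given relative to the median of all tested genes. Members were also adjusted by list, over its tested members alone. Genes named in the text were the 12 highest and 12 lowest log2 changes among genes past the threshold with a mean of at least 5 FPKM in the higher group and no overlap between the groups, predicted genes left out, and where fewer than 5 passed in a direction the tables hold the 5 leading genes as not passed, of which the text names some or none. For these genes the lack of overlap is thus set by selection. List members past the threshold and the 4 leading members of each list were added to these.

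The procedure was tested on simulated data in which 50 genes per size were shifted. Of genes shifted by 1 on the log2 scale it recovered 60% in morulae, 40% in ICM-labelled and 40% in TE-labelled libraries. Of those shifted by 1.5 it recovered 96%, 84% and 74%, and of those shifted by 2 it recovered 100%, 94% and 98%; wrong calls were 18 of 196, 14 of 173 and 10 of 166. Alternatives covered the pseudocount, the filter, scaling between libraries, the variance model, array weights, the libraries in the fit, a replicate block, each library left out, and the list test; 5 more, on certain genes, a pair of libraries and trends with length and GC content, were added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. No library was left out of the main results.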

Results

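RNA of mouse embryos (ICR strain) cultured in G1-Plus medium with or without nicotine was profiled by Smart-seq2, a full-length messenger RNA method for very small inputs. The 13 libraries comprised 2 control and 3 nicotine libraries of morulae, the stage of compacted cells before the blastocyst cavity forms. Inner cell mass (ICM), which gives rise to the embryo proper, and trophectoderm (TE), which gives rise to the placenta, had 2 control and 2 nicotine libraries each. The protocol names 1 mM and 1.5 mM nicotine and 15 embryos from each of the treated and control groups per stage. It does not say which dose each library received. Expression was deposited as FPKM for 27557 genes, with no read counts, so the depth of each library is unknown. The FPKM sums ranged from 399321 to 545772 per library, and the genes at 1 FPKM or more from 7435 in control morula 2 to 10468 in nicotine TE 2. Genes above 0 numbered 22189 in control ICM 2 and 12970 to 16089 in the other 12 libraries. Libraries are named by group and replicate number. Nothing in the labels says that replicates came from separate cultures or animals.

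Stage was the main axis of variation: the first principal component held 62.5% of the variance and parted morulae from ICM-labelled and TE-labelled libraries. The list of nicotinic acetylcholine receptors (3 of 16 members expressed) and that of cumulus and granulosa cell markers (3 of 20) were too sparse to test. Libraries of the same group correlated at 0.954 to 0.983 across genes (log2 values, 8 pairs), and libraries of the same stage and different treatment at 0.944 to 0.972 (14 pairs). The 13 mitochondrially encoded genes were regular in the morula libraries and erratic in the others. mt-Cytb, the cytochrome b gene, stood at 22352 FPKM in control ICM 1 and 561 FPKM in control ICM 2. Sex-linked genes set a pair of libraries apart: nicotine TE 2 held Eif2s3y, a Y-linked gene, at 0.819 FPKM and Xist, the RNA of the inactive X chromosome, at 52.5 FPKM. Nicotine ICM 1 held them at 69.6 FPKM and 0.992 FPKM.

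Nicotine and control morulae were compared first. Nicotine morulae held more mRNA of 5 of 34 genes of the integrated stress and unfolded protein response. Chac1, which encodes a glutathione-degrading enzyme of the integrated stress response, rose to 21.6 ± 11.7 FPKM (SD, n = 3) against 2.24 ± 2.31 FPKM (SD, n = 2) in control morulae. Trib3, a pseudokinase induced by the same response, rose (6.21 ± 1.79 FPKM against 1.00 ± 0.795), as did its transcription factor Atf4 (65.3 ± 10.4 FPKM against 27.9 ± 1.82). Slc3a2, the heavy chain of several amino acid transporters, rose too (152 ± 34.9 FPKM against 56.5 ± 0.0369). Of the same list 1 gene fell, Hsp90b1, the chaperone GRP94 of the endoplasmic reticulum (23.1 ± 5.19 FPKM against 78.9 ± 5.86). Messenger RNAs of ribosomal proteins and the respiratory chain fell as lists by camera (calls lost with an estimated correlation).

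By limma, 254 of 11386 tested genes passed the threshold, 147 higher and 107 lower, and the median change of all tested genes was 0.12 on the log2 scale. At an unadjusted p under 0.05 there were 1778 genes, where chance alone gives 569. In the mm10 annotation, the leading genes were Chac1 (ENSMUSG00000027313, chromosome 2, 119351229 to 119354381), Apoe (ENSMUSG00000002985, chromosome 7, 19696109 to 19699188), Nupr1 (ENSMUSG00000030717, chromosome 7, 126623249 to 126630861) and Xlr3a (ENSMUSG00000057836, chromosome X, 73086293 to 73097095). Chac1 changed by 2.84 on the log2 scale (limma adjusted p = 0.0254). Apoe, the lipid-carrying apolipoprotein E, rose by 2.04 (28.4 ± 6.59 FPKM against 6.01 ± 0.0337; limma adjusted p = 0.00946). Nupr1, a stress-induced chromatin-binding protein, rose by 2.30 (8.58 ± 0.579 FPKM against 1.06 ± 0.960; limma adjusted p = 0.0112). Xlr3a, of an X-linked multi-copy family, fell by 2.20 (20.1 ± 0.965 FPKM against 97.6 ± 23.7; limma adjusted p = 0.00255). Chac1 kept its call in 20 of 30 alternatives (limma adjusted p up to 0.202), but not without control morula 1 or 2 or nicotine morula 1 or 2. Apoe kept its call in 26 of 30 alternatives (limma adjusted p up to 0.144), but not without control morula 1 or 2. Nupr1 kept its call in 25 of 29 alternatives (limma adjusted p up to 0.169), but not without control morula 1 or nicotine morula 1, while Xlr3a held without any 1 library.

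Other genes that rose with nicotine in morulae included Ccpg1, a receptor for autophagy of the endoplasmic reticulum (20.2 ± 3.41 FPKM against 4.32 ± 1.52), and Btg1, an antiproliferative factor (19.8 ± 7.37 FPKM against 4.55 ± 0.789). Ptdss2, a phosphatidylserine synthase, rose as well (49.8 ± 15.0 FPKM against 13.8 ± 3.12). Fcgr3, an immunoglobulin Fc receptor, stood at 7.45 ± 1.40 FPKM against 1.17 ± 0.333. Hsd17b14, a steroid dehydrogenase, stood at 24.4 ± 4.44 FPKM against 5.62 ± 2.19, and the mRNA export factor Nxf2 at 5.87 ± 3.46 FPKM against 0.0592 ± 0.0837. Ly6i rose to 6.10 ± 1.03 FPKM and was listed at 0 in both controls. Tdpoz5 rose to 5.48 ± 2.22 FPKM against 0.316 ± 0.137. Spic, an ETS transcription factor of the epiblast and inner cell mass marker list, rose (732 ± 115 FPKM against 310.1 ± 83.9). Among genes that fell were Xlr3b (7.53 ± 0.595 FPKM against 30.3 ± 8.45) and Xlr3c (6.27 ± 1.15 FPKM against 32.4 ± 8.29). They share sequence with Xlr3a and overlap Xlr5a, so that their values are not independent. Dbi, the acyl-CoA binding protein (11.8 ± 7.48 FPKM against 30.7 ± 1.57), and Bola3, a factor of mitochondrial iron-sulfur cluster assembly (7.47 ± 0.977 FPKM against 21.7 ± 3.93), also fell. Cnpy2 (4.11 ± 0.188 FPKM against 12.9 ± 4.19) and Nlrp4c (2.25 ± 0.353 FPKM against 7.92 ± 0.299) fell as well. So did Smim11 (6.22 ± 2.16 FPKM against 20.8 ± 6.13), Tmem256 (4.28 ± 1.75 FPKM against 12.7 ± 0.853) and Wfdc15a (11.4 ± 2.56 FPKM against 36.6 ± 7.32). Appbp2os, which overlaps Appbp2, fell too (2.13 ± 0.251 FPKM against 8.29 ± 3.87).

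Of 30 gene lists tested, 5 passed by camera with its preset correlation in morulae and 0 with an estimated correlation (by fry, 4). All 58 ribosomal protein genes had lower fitted means with nicotine, with a list median of -0.71 (log2) relative to all tested genes (camera adjusted p = 9.93e-44, or 0.203 with an estimated correlation). Of these, 12 fell and 46 did not pass, and 45 fell when adjusted by list. Rps18 stood at 288 ± 60.7 FPKM against 480.0 ± 30.6 and Rps14 at 1348 ± 207 FPKM against 2279 ± 9.58. Of the 62 nuclear genes of oxidative phosphorylation, 10 fell and 52 did not pass (list median -0.53; camera adjusted p = 7.16e-19, or 0.246 with an estimated correlation). Adjusted over the list alone, 21 fell. Atp5e, a subunit of ATP synthase, stood at 68.7 ± 12.5 FPKM against 139.7 ± 17.8, and Cox7c, of cytochrome c oxidase, at 149 ± 25.7 FPKM against 276 ± 39.3. All 13 mitochondrially encoded genes had lower fitted means as well, and as a list they did not pass (-0.59; camera adjusted p = 0.061). This p draws on a variance over all stages, the erratic ones included, so it cannot judge morulae alone. The summed FPKM of these genes was 69218 and 65072 in control and 41220 to 53942 in nicotine morulae. With these genes removed and the libraries rescaled, the medians were -0.69 for ribosomal protein genes and -0.51 for oxidative phosphorylation. Rescaling hardly moves such medians, so this decides nothing about mitochondrial content. Lysosome and autophagy genes rose as a list (0.40; camera adjusted p = 3.42e-07, or 0.246 with an estimated correlation), with 8 of 47 passing, 17 when adjusted by list. Those that passed included Lamp2 (152 ± 17.2 FPKM against 89.9 ± 3.57) and the cathepsin Ctsb (51.6 ± 18.0 FPKM against 19.7 ± 1.88). The p53 target list (0.42; camera adjusted p = 4.79e-07, or 0.298 with an estimated correlation) held 1 of 28 members past the threshold, Psrc1. This spindle protein gene stood at 19.4 ± 3.32 FPKM against 9.19 ± 0.863, and 9 members were higher when adjusted by list. None of the 14 immediate early genes passed in limma, 6 did when adjusted by list, and the list rose (0.55; camera adjusted p = 0.000972, or 0.424 with an estimated correlation).

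The list of the integrated stress and unfolded protein response had members on both sides: 5 of 34 rose (Slc3a2, Chac1, Nupr1, Trib3 and Atf4), 1 fell (Hsp90b1) and 28 did not pass. As a list it did not pass (0.29; camera adjusted p = 0.132), and 11 were higher and 5 lower when adjusted by list. Notch pathway genes, named in the title of the series, had a list median of 0.05 (camera adjusted p = 0.51), and 0 of 33 passed by limma in morulae. Hes1, a transcriptional target of Notch, stood at 26.1 ± 5.67 FPKM against 14.2 ± 2.93. Cldn4, a claudin of the trophectoderm, rose (122 ± 42.2 FPKM against 55.8 ± 5.04), as did H2afx, the histone variant of the DNA damage response (95.2 ± 47.9 FPKM against 30.8 ± 2.75). Txn1, thioredoxin, fell (171 ± 28.1 FPKM against 377 ± 15.1).

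The morula count rested on single libraries: it was 108 without control TE 1 or 2, 27 without control morula 1, 12 without control morula 2 and 17 without nicotine morula 1, against 254 with all libraries. Higher and lower genes numbered 53 and 55 without control TE 1 or 2 and 78 and 144 without nicotine morula 3, against 147 and 107. Only the groups compared gave 0 genes by limma (1624 at an unadjusted p under 0.05), no filter gave 23, no intensity trend 32, array weights 396, a replicate block 23 and removal of a length trend 109, and the split of higher and lower genes was 179 and 65 at the same sum (median of all genes 0.19), 57 and 150 after centring on the median (-0.05), 32 and 72 after quantile normalization (0.01) and 83 and 135 after removal of a GC trend (5e-04).

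**Figure D1:**
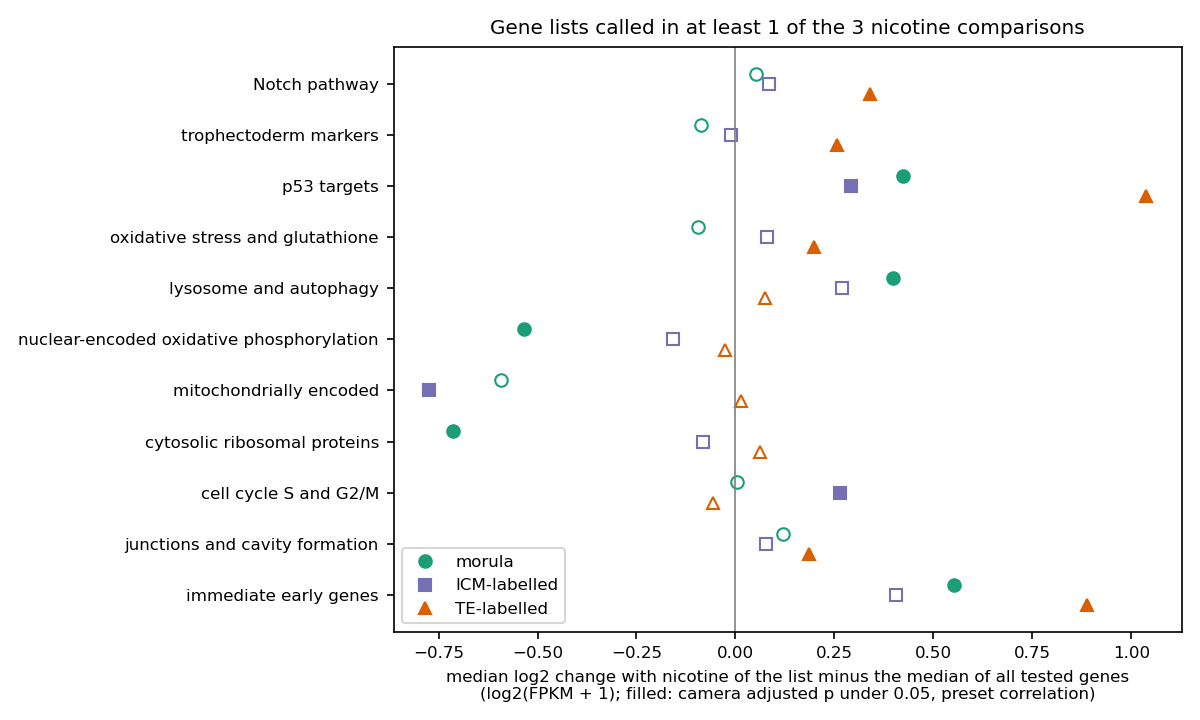
Median log2 change with nicotine of each gene list minus the median of all tested genes (horizontal axis, log2), for the lists that passed in at least 1 of the 3 stages, with filled points for camera adjusted p under 0.05 at the preset correlation. Ribosomal protein genes lay at -0.71 in morulae and p53 targets at 1.04 in TE-labelled libraries, and 0 lists passed with an estimated correlation.

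TE-labelled libraries were compared next. Nicotine TE-labelled libraries held more mRNA of genes that p53, the tumour suppressor activated by DNA damage, is known to induce (as a list, camera adjusted p = 1.05e-17, or 0.171 with an estimated correlation). Fas, a death receptor, rose to 7.93 ± 1.18 FPKM (SD, n = 2) against 0.305 ± 0.258 FPKM (SD, n = 2) in control TE-labelled libraries. Cdkn1a, the cell cycle inhibitor p21, rose to 177 ± 10.8 FPKM (SD, n = 2) against 56.4 ± 21 FPKM (SD, n = 2). Ly6a, a surface antigen of stem cells (2339 ± 489.6 FPKM against 475 ± 35.9), and the claudin Cldn6 (282 ± 119 FPKM against 61.6 ± 1.44) rose too. Among genes that fell was Canx, the chaperone calnexin (32.4 ± 1.26 FPKM against 174 ± 23.9). Eif1a, a translation initiation factor (30.4 ± 4.61 FPKM against 152 ± 10.8), and Spic (53.7 ± 16.4 FPKM against 245 ± 31.0) fell as well.

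In limma 40 genes passed, 25 higher and 15 lower, with a median change of -0.01 over all tested genes, and 1361 genes had an unadjusted p under 0.05. In mm10 the leading genes were Fas (ENSMUSG00000024778, chromosome 19, 34290666 to 34327772), Cdkn1a (ENSMUSG00000023067, chromosome 17, 29090976 to 29100727), Ly6a (ENSMUSG00000075602, chromosome 15, 74994877 to 74998031), Canx (ENSMUSG00000020368, chromosome 11, 50293961 to 50325673) and Eif1a (ENSMUSG00000057561, chromosome 18, 46597701 to 46616456). Fas changed by 2.78 on the log2 scale (limma adjusted p = 0.000985), Cdkn1a by 1.68 (limma adjusted p = 0.0239) and Ly6a by 2.28 (limma adjusted p = 0.000985). Canx fell by 2.38 (limma adjusted p = 0.000985) and Eif1a by 2.29 (limma adjusted p = 0.00038). Cdkn1a kept its call in 20 of 30 alternatives (limma adjusted p up to 0.261), but not without control TE 1 or nicotine TE 1 or 2, while Fas, Ly6a, Canx and Eif1a held without any 1 library.

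Apoe rose in TE-labelled libraries as well (259 ± 23.0 FPKM against 46.9 ± 3.82; log2 change 2.44; limma adjusted p = 0.0046). Cd81, a tetraspanin, rose (67.7 ± 4.35 FPKM against 6.97 ± 4.97), as did Gab1, an adaptor of growth factor receptors (10.2 ± 3.55 FPKM against 0.804 ± 0.159). Rtkn, a Rho effector that overlaps Wdr54, rose too (13.8 ± 1.91 FPKM against 1.36 ± 1.35). Ptp4a3, a protein tyrosine phosphatase of the p53 target list, stood at 11.3 ± 0.474 FPKM against 1.80 ± 0.366. The claudin Cldn9 stood at 23.8 ± 13.2 FPKM against 3.24 ± 0.284 and the hyaluronidase Hyal1, which overlaps Naa80, at 8.48 ± 1.69 FPKM against 1.24 ± 0.620. Cox6b2, a subunit of cytochrome c oxidase, rose (17.9 ± 3.40 FPKM against 1.70 ± 0.0933), as did Ier3, an immediate early gene (17.5 ± 4.88 FPKM against 3.63 ± 0.626). Ftl1, the ferritin light chain, rose as well (5168 ± 360.2 FPKM against 1967 ± 54.5). mt-Cytb passed (10221 ± 2445 FPKM against 249 ± 7.80), but its values were erratic between control ICM-labelled replicates. Larp1, a regulator of the translation of ribosomal protein mRNAs, fell (2.22 ± 0.341 FPKM against 21.1 ± 4.32), as did Paip1, a partner of the poly(A)-binding protein (2.20 ± 0.113 FPKM against 16.1 ± 9.44). So did Siah1b, a ubiquitin ligase (2.75 ± 1.15 FPKM against 14.9 ± 0.342), and the mitochondrial ferredoxin Fdx1 (42.3 ± 20.2 FPKM against 121 ± 14.4). Tmem230 (6.92 ± 3.16 FPKM against 27.9 ± 2.86), Ccdc160 (3.60 ± 0.907 FPKM against 14.3 ± 0.634), and Ube2dnl1 (0.381 ± 0.392 FPKM against 6.15 ± 0.604) also fell. Xlr3a (34.2 ± 8.54 FPKM against 98.4 ± 13.2) and Olfr1270, which overlaps Gm4222 (0.0104 ± 0.00857 FPKM against 25.4 ± 4.14), were lower too.

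With the preset correlation of camera 6 of 30 lists passed in TE-labelled libraries, all of them higher, and with an estimated correlation 0 (by fry, 1). The p53 target list had the largest shift of the 6, 1.04 (log2) relative to all tested genes (camera adjusted p = 1.05e-17, or 0.171 with an estimated correlation). Of its 28 members 3 rose (Cdkn1a, Fas and Ptp4a3), 25 did not pass, and 18 were higher when adjusted by list. Immediate early genes rose as a list (0.89; camera adjusted p = 2e-08, or 0.339 with an estimated correlation), with 1 of 14 passing, 6 when adjusted by list; Btg2 stands in both lists. Trophectoderm markers shifted by 0.26 (camera adjusted p = 0.0194, or 0.666 with an estimated correlation), and 0 of 27 passed by limma. Adjusted over the list alone, 5 were higher (Gata2, Krt19, Krt7, Cldn4 and Krt8) and Eomes was lower. Genes of cell junctions and cavity formation (0.19; camera adjusted p = 0.0286, or 0.666 with an estimated correlation) had 1 of 31 past the threshold, Cldn6, and 4 when adjusted by list. Oxidative stress and glutathione genes (0.20; camera adjusted p = 0.0177, or 0.666 with an estimated correlation) had 1 of 34, Ftl1, and 3 when adjusted by list. Epiblast and inner cell mass markers did not pass as a list (-0.25; camera adjusted p = 0.112), although Spic fell. Nanog, a pluripotency factor, stood at 184 ± 8.07 FPKM against 327 ± 21.1.

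Notch pathway genes shifted higher as a list in TE-labelled libraries (0.34; camera adjusted p = 0.00616, or 0.666 with an estimated correlation). Of the 33 tested members 27 had a fitted change above 0, and by limma 0 passed over all genes and 0 when adjusted by list. The receptor gene Notch1 stood at 4.58 ± 0.629 FPKM against 1.10 ± 0.117 (limma adjusted p = 0.129). Hes1 stood at 38.2 ± 10.4 FPKM against 17.3 ± 0.215 (limma adjusted p = 0.188). Their groups did not overlap, which chance gives for 33.3% of genes. The ligand Jag2 stood at 2.91 ± 1.58 FPKM against 1.27 ± 0.454. Placental trophoblast markers did not pass as a list (0.45; camera adjusted p = 0.0501).

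Left-out libraries moved the TE count: it was 62 without control ICM 1, 64 without control ICM 2, 9 without control TE 1, 23 without control TE 2, 24 without nicotine TE 2 and 18 without nicotine morula 1, against 40. Its higher and lower genes numbered 30 and 29 without nicotine TE 1, 12 and 12 without nicotine TE 2 and 22 and 9 without nicotine morula 2, against 25 and 15. Trophectoderm markers did not pass without control TE 2 or nicotine TE 2 (0.12 to 0.35) and moved to 0.47 without control TE 1 and 0.51 without nicotine TE 1. Junctions and cavity formation did not pass without control TE 1 or 2 or nicotine TE 2 (0.08 to 0.16) and moved to 0.32 without nicotine TE 1. Notch pathway genes did not pass without control TE 2 or nicotine TE 2 (0.31 to 0.33). Oxidative stress genes did not pass without control TE 2 or nicotine TE 2 (0.16 to 0.25). A pseudocount of 0.1 gave 10 genes and of 5 gave 99, the stricter filter 24, only the groups compared 6, a replicate block 13 and removal of a GC trend 23, and centring on the median split 58 genes into 43 higher and 15 lower.

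**Figure D2:**
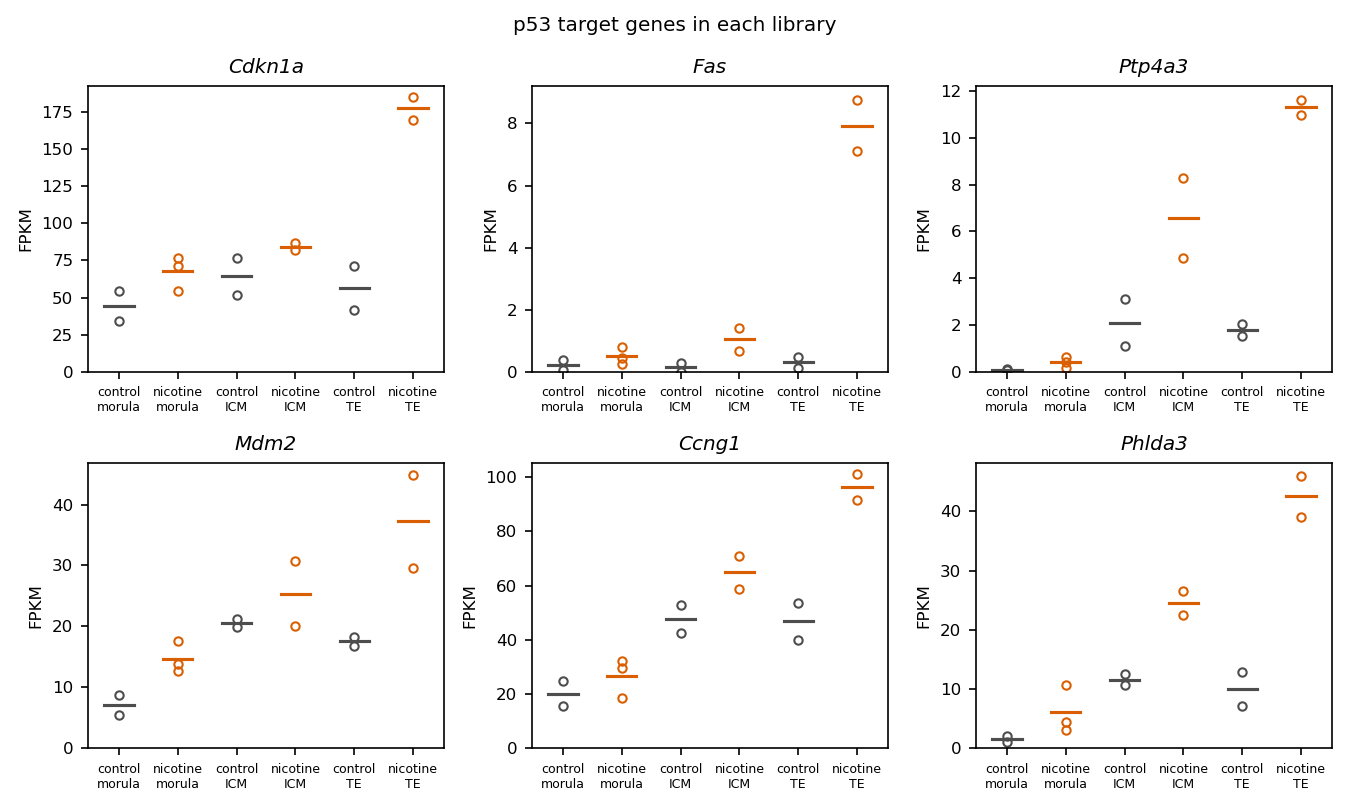
Expression of 6 p53 target genes (vertical axes, FPKM from 0) in each library (circles) of the 6 groups, with horizontal bars at the group means. Cdkn1a stood at 177 FPKM on average in nicotine TE-labelled libraries and at 56.4 FPKM in control TE-labelled libraries.

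The ICM-labelled libraries carry the label of the lineage of the embryo proper, and the same limit on cell shares holds for them. Larp1 rose with nicotine to 19.7 ± 7.75 FPKM (SD, n = 2) against 1.69 ± 0.327 FPKM (SD, n = 2) in control ICM-labelled libraries. Pkm, the glycolytic enzyme pyruvate kinase, rose to 137 ± 21.2 FPKM (SD, n = 2) against 49.0 ± 1.18 FPKM (SD, n = 2). Khdc3, of the maternal complex beneath the oocyte cortex, rose to 822 ± 56.0 FPKM (SD, n = 2) against 387 ± 37.1 FPKM (SD, n = 2). Pramel5, of a multi-copy family expressed in germ cells and early embryos, fell to 66.2 ± 5.55 FPKM (SD, n = 2) against 160.3 ± 27.8 FPKM (SD, n = 2).

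Here limma passed 19 genes, 16 higher and 3 lower, with a median change of 0.11 over all tested genes and 1656 genes at an unadjusted p under 0.05. Larp1 (ENSMUSG00000037331, chromosome 11, 58009064 to 58062034) changed by 2.90 on the log2 scale (limma adjusted p = 0.017). Pkm (ENSMUSG00000032294, chromosome 9, 59656368 to 59679375) changed by 1.46 (limma adjusted p = 0.0185). Khdc3 changed by 1.09 (limma adjusted p = 0.0253) and Pramel5 by -1.25 (limma adjusted p = 0.0365). Larp1, Pkm, Khdc3 and Pramel5 kept their calls in 28, 24, 16 and 15 of 30 alternatives (limma adjusted p up to 0.185 for each). None held without control ICM 2. Pkm, Khdc3 and Pramel5 were also lost without control ICM 1 or nicotine ICM 1. Khdc3 and Pramel5 were also lost without nicotine ICM 2 or nicotine morula 1, and Pramel5 without control TE 1. Atn1, the transcriptional corepressor atrophin, rose (17.5 ± 6.16 FPKM against 2.40 ± 0.252). Sf3a2, a splicing factor gene that overlaps Plekhj1 (9.66 ± 3.75 FPKM against 1.07 ± 0.0247), and Pltp, the phospholipid transfer protein, which overlaps Ctsa (6.80 ± 1.26 FPKM against 1.37 ± 0.397), rose as well. So did Ffar3, a receptor for short-chain fatty acids (9.35 ± 0.112 FPKM against 0.785 ± 0.475), and Marcksl1, an actin-binding protein (109.8 ± 19.4 FPKM against 34.4 ± 2.16). Ppp1r18, a phosphatase regulator, rose (16.4 ± 6.60 FPKM against 2.64 ± 0.318). Snx30, a sorting nexin, stood at 18.3 ± 1.06 FPKM against 4.24 ± 1.59. Ubald2 stood at 19.7 ± 2.93 FPKM against 4.18 ± 0.707 and the histone gene Hist3h2ba at 6.49 ± 3.26 FPKM against 0.767 ± 0.0405. Snord52, a small nucleolar RNA within the host gene 1110038B12Rik, rose (5.89 ± 0.694 FPKM against 0.529 ± 0.277). Zfp934, which overlaps Zfp935, fell (1.88 ± 0.121 FPKM against 9.88 ± 2.22). Il6, an interleukin named after its values were seen, fell too (0 in both nicotine libraries against 2.20 ± 0.793 FPKM). mt-Co1 was 0 there too, so this fall is uncertain. Paip1, which did not pass, stood at 1.69 ± 0.363 FPKM against 10.4 ± 1.78, and Chd8 at 3.10 ± 1.06 against 9.84 ± 1.80.

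By camera with the preset correlation 3 lists passed in ICM-labelled libraries, and with an estimated correlation 0 (by fry, 0). Cell cycle genes of S and G2/M phase shifted higher (0.26; camera adjusted p = 0.00558, or 0.385 with an estimated correlation), with 0 of 42 members past the threshold in limma and 1, Nusap1, when adjusted by list. The p53 target list shifted by 0.29 (camera adjusted p = 0.0441, or 0.78 with an estimated correlation), with 0 of 28 past the threshold and 4 (Bbc3, Plk2, Ptp4a3 and Psrc1) when adjusted by list. Mitochondrially encoded genes, erratic in these libraries, shifted by -0.77 (camera adjusted p = 0.0142, or 0.3 with an estimated correlation), with 0 of 13 past the threshold and 1 lower when adjusted by list. The Notch list did not pass (0.09; camera adjusted p = 0.312), nor did cholesterol and fatty acid synthesis (0.38; camera adjusted p = 0.0506).

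The ICM count was 2 without control ICM 2, 9 without nicotine ICM 1, 53 without nicotine TE 1, 56 without nicotine TE 2, 5 without nicotine morula 1 and 31 without nicotine morula 2, against 19, with 15 and 8 without control ICM 1, 0 and 2 without control ICM 2, 16 and 5 without control TE 2 or control morula 2, 12 and 8 without nicotine ICM 2 and 22 and 6 without control morula 1 in higher and lower genes, against 16 and 3. The p53 targets did not pass without control ICM 2 or nicotine ICM 1 or 2 (0.21 to 0.44) and moved to 0.52 without control ICM 1. Mitochondrially encoded genes did not pass without control ICM 2 or nicotine ICM 1 or 2 (-1.15 to -0.16). Cell cycle genes did not pass without control ICM 2 (0.13) and moved to 0.17 without nicotine ICM 1. With a pseudocount of 0.1 the count was 4 and with 5 it was 104, with no filter 99, with the stricter filter 10, with only the groups compared 1, with robust empirical Bayes 36, with a replicate block 4 and with array weights 11, and higher and lower genes numbered 29 and 12 at the same sum, 10 and 5 after centring on the median, 17 and 13 after quantile normalization and 9 and 9 after removal of a GC trend.

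**Figure D3:**
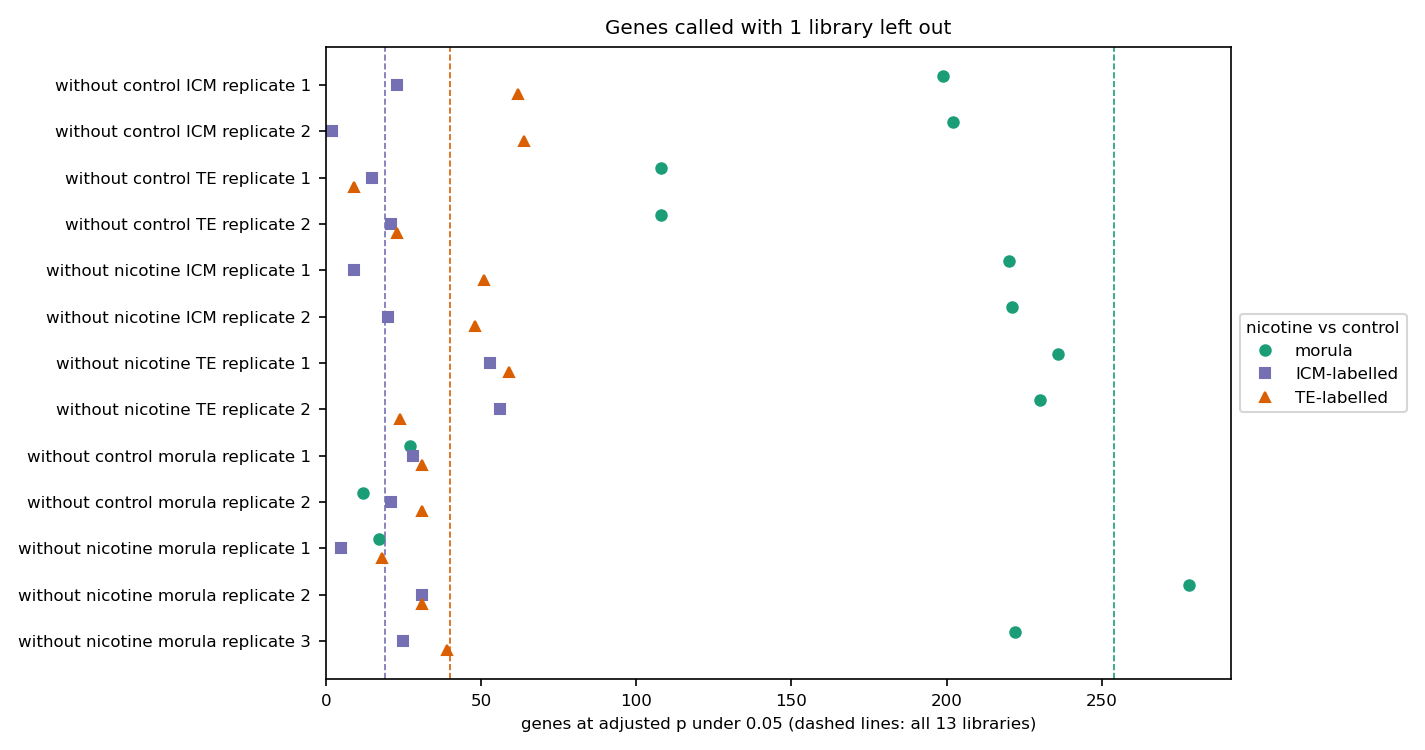
Number of genes past the limma threshold (horizontal axis) in each nicotine comparison with 1 library left out (vertical axis), with dashed lines at the counts with all 13 libraries. The morula count fell from 254 to 12 without control morula 2, and the ICM-labelled count from 19 to 2 without control ICM 2.

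As lists, lineage markers did not part the control ICM-labelled and TE-labelled libraries. Krt18, a trophectoderm keratin, averaged 365 ± 226 against 355 ± 91.2 FPKM (SD, n = 2 each) in ICM-labelled and TE-labelled libraries. Control ICM 1 and 2 (205 and 525 FPKM) lay either side of both TE values. Mean Krt8 was as even (261 ± 118 FPKM against 267 ± 46.3). Cdx2, a trophectoderm factor, stood at 2.48 ± 1.02 FPKM against 3.92 ± 0.396, and Nanog at 222 ± 17.9 FPKM against 327 ± 21.1. Larp1 was lower in ICM-labelled libraries (1.69 ± 0.327 FPKM against 21.1 ± 4.32), and Hist1h1b, a linker histone, higher (24.1 ± 4.92 FPKM against 3.78 ± 0.0665).

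In limma 12 genes passed, 3 higher and 9 lower in ICM-labelled libraries, with a median of -0.26 over all tested genes and 1608 genes at an unadjusted p under 0.05. The last count was 760 at the same sum, 957 after centring on the median and 906 after quantile normalization. Larp1 changed by -3.03 on the log2 scale (limma adjusted p = 0.00803) and Hist1h1b (ENSMUSG00000058773, chromosome 13, 21779883 to 21780625) by 2.38 (limma adjusted p = 0.0199). Also higher were Gab1 (8.03 ± 0.271 FPKM against 0.804 ± 0.159) and Snrnp70, a protein of the U1 spliceosome particle (22.8 ± 3.93 FPKM against 5.15 ± 1.38). Lower were Srebf2, the transcription factor of cholesterol synthesis (3.10 ± 0.369 FPKM against 16.3 ± 2.08), and Msmo1, an enzyme of that pathway (36.5 ± 3.96 FPKM against 106 ± 20.2). Snord52 (0.529 ± 0.277 FPKM against 8.49 ± 3.77), Snx30 (4.24 ± 1.59 FPKM against 28.1 ± 6.09) and Eny2 (51.1 ± 3.80 FPKM against 159 ± 9.38) were lower too. So were Mrps24, which overlaps Urgcp (63.8 ± 1.03 FPKM against 172 ± 0.324), and Mfsd14a (45.8 ± 4.38 FPKM against 104 ± 12.6). Larp1 kept its call in 26 of 30 alternatives and Hist1h1b in 25 of 30 (limma adjusted p up to 0.0764 and 0.165). Neither held without control ICM 2 or control TE 1 or 2.

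Relative to all tested genes, trophectoderm markers had a median of -0.10 (camera adjusted p = 0.718) and epiblast markers of -0.14 (camera adjusted p = 0.824), and 0 members of either list passed by limma. Of 30 lists 7 passed by camera and 0 with an estimated correlation (by fry, 0). Lower in ICM-labelled libraries were ribosomal protein genes as a list (-0.20; camera adjusted p = 2.74e-10, or 0.93 with an estimated correlation; 0 of 58 past the threshold, 14 when adjusted by list). Oxidative phosphorylation was lower too (-0.18; camera adjusted p = 2.82e-07, or 0.93 with an estimated correlation; 0 of 62 past the threshold, 11 when adjusted by list). So was cholesterol and fatty acid synthesis (-0.19; camera adjusted p = 0.00151, or 0.93 with an estimated correlation; 2 of 32 lower, 11 when adjusted by list). The stress response list was lower (-0.23; camera adjusted p = 0.0248, or 0.988 with an estimated correlation), with 0 of 34 past the threshold and 0 when adjusted by list. Lysosome and autophagy was lower too (-0.18; camera adjusted p = 0.0396, or 0.988 with an estimated correlation), with 0 of 47 past the threshold and 5 when adjusted by list. Higher were immediate early genes (0.30; camera adjusted p = 0.00264, or 0.93 with an estimated correlation), with 0 of 14 past the threshold and 0 when adjusted by list. The erratic mitochondrially encoded genes were higher too (0.68; camera adjusted p = 5.08e-05, or 0.057 with an estimated correlation), with 0 of 13 past the threshold and 1, mt-Cytb, when adjusted by list. Cholesterol synthesis did not pass without control ICM 2 (-0.24) and moved to -0.37 without control ICM 1 and -0.29 without control TE 1. Lysosome and autophagy did not pass without control ICM 1 or 2, control TE 2, nicotine ICM 1 or 2 or nicotine TE 1 or 2 (-0.18 to -0.14). Oxidative phosphorylation moved to -0.06 without control ICM 1 and -0.30 without control ICM 2. Immediate early genes did not pass without control ICM 1 or control TE 1 (0.22 to 0.23) and moved to 0.54 without control ICM 2. The stress response list did not pass without control ICM 2 or control TE 1 (-0.23 to -0.22). Mitochondrially encoded genes moved to 0.30 without control ICM 2, 1.24 without control TE 1 and 0.45 without control TE 2. This count was 22 without control ICM 1, 7 without control ICM 2, 5 without control TE 1 and 1 without control TE 2, against 12. It was 73 with no filter, 2 with only the groups compared, 90 with array weights, 22 without nicotine TE 2 and nicotine ICM 1 together, 5 without a length trend and 4 without a GC trend (2 higher and 2 lower), and the split was 3 higher and 4 lower at the same sum (median of all genes -0.04) and after quantile normalization (0.0017), and 3 and 3 after centring on the median (0.06).

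**Figure D4:**
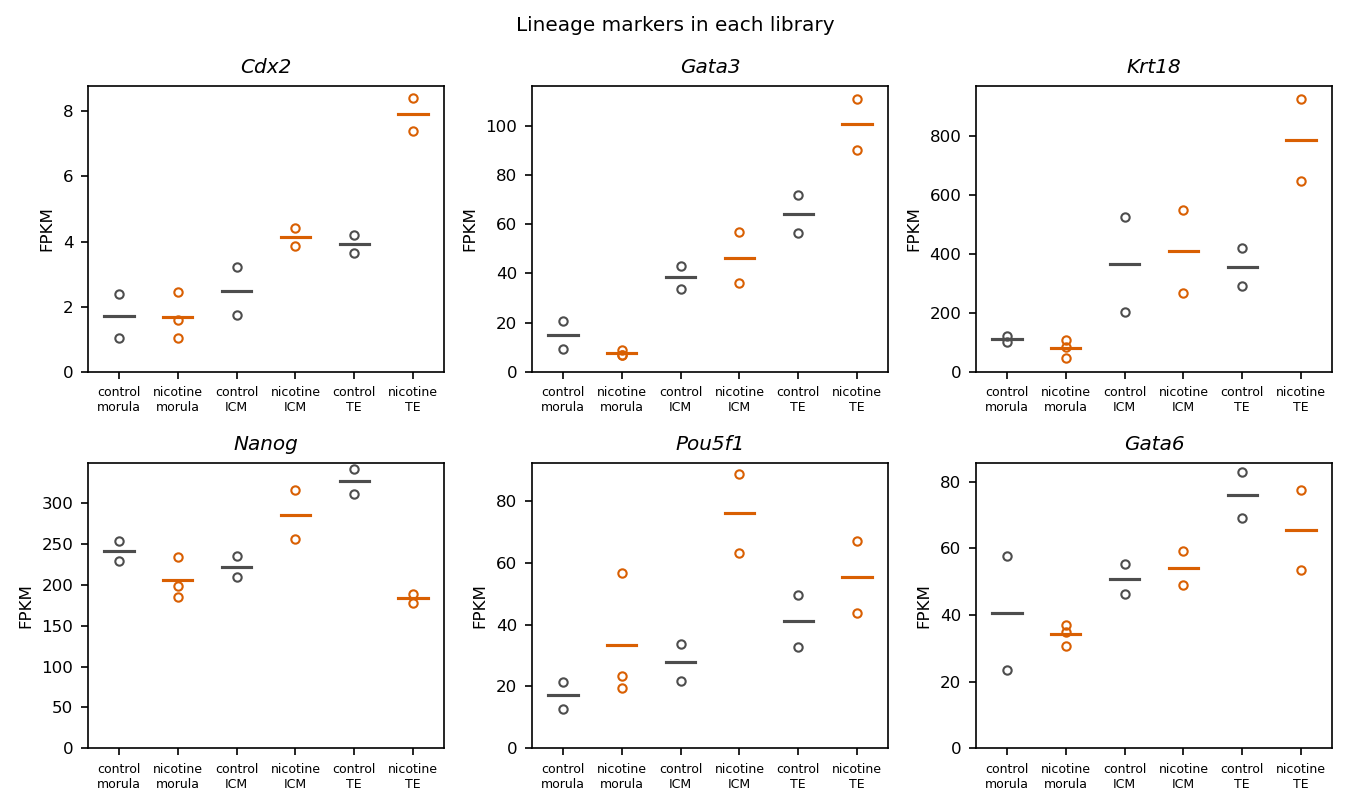
Expression of 6 lineage markers (vertical axes, FPKM from 0) in each library (circles) of the 6 groups, with horizontal bars at the group means. Krt18 stood at 365 FPKM on average in control ICM-labelled and 355 FPKM in control TE-labelled libraries.

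In nicotine embryos the ICM-labelled and TE-labelled libraries differed in trophectoderm markers and p53 targets by camera (calls lost with an estimated correlation). Lower in ICM-labelled libraries were Gata2, a transcription factor of trophoblast (0.290 ± 0.208 FPKM against 2.13 ± 0.426), Gdf15, a stress-induced cytokine (0.405 ± 0.572 FPKM against 4.29 ± 0.784), and Fas (1.04 ± 0.506 FPKM against 7.93 ± 1.18). Cldn7, a claudin (227 ± 2.39 FPKM against 462 ± 66.7), and Ly6a (859 ± 297 FPKM against 2339 ± 489.6) were lower as well. Larp1 (19.7 ± 7.75 FPKM against 2.22 ± 0.341) and Eif1a (97.7 ± 4.40 FPKM against 30.4 ± 4.61) were higher. So were Canx (95.2 ± 27.1 FPKM against 32.4 ± 1.26) and Spic (133 ± 44.7 FPKM against 53.7 ± 16.4).

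Of 153 genes that passed by limma 35 were higher and 118 lower in ICM-labelled libraries, with a median of -0.12 over all tested genes and 1695 at an unadjusted p under 0.05. The log2 differences of these examples were -1.28 for Gata2 (limma adjusted p = 0.0325), -1.97 for Gdf15 (limma adjusted p = 0.0197) and 2.64 for Larp1 (limma adjusted p = 0.0147). By camera 6 of 30 lists passed, and 0 with an estimated correlation (by fry, 0). Trophectoderm markers had a median of -0.67 relative to all tested genes (camera adjusted p = 0.00011, or 0.415 with an estimated correlation), with 1 of 27 lower, Gata2, and 6 when adjusted by list. The p53 list had a median of -0.43 (camera adjusted p = 2.55e-05, or 0.415 with an estimated correlation), with 4 of 28 lower (Perp, Tnfrsf10b, Fas and Gdf15) and 8 when adjusted by list. Junction genes (-0.39; camera adjusted p = 0.00351, or 0.49 with an estimated correlation) were lower, with 1 of 31 past the threshold, Cldn7, and 1 when adjusted by list. Ribosomal protein genes were lower (-0.37; camera adjusted p = 1.19e-12, or 0.415 with an estimated correlation), with 2 of 58 past the threshold (Rps29 and Rpl26) and 27 when adjusted by list. Oxidative phosphorylation was as well (-0.27; camera adjusted p = 7.18e-06, or 0.49 with an estimated correlation), with 2 of 62 past the threshold (Cox5a and Cox7c) and 18 when adjusted by list. Cell cycle genes were higher (0.33; camera adjusted p = 0.000598, or 0.415 with an estimated correlation), with 0 of 42 past the threshold and 0 when adjusted by list. Junctions and cavity formation did not pass without nicotine ICM 2 (-0.22) and moved to -0.61 without nicotine ICM 1 and -0.21 without nicotine TE 2. Trophectoderm markers moved to -0.42 without nicotine ICM 2. The p53 targets moved to -0.28 without nicotine TE 1 and -0.71 without nicotine TE 2. Gata2 kept its call in 10 of 29 alternatives (limma adjusted p up to 0.306), but not without control TE 2, nicotine ICM 1 or 2, nicotine TE 1 or 2, control morula 1 or 2 or nicotine morula 1 or 2. Gdf15 kept its call in 21 of 29 alternatives (limma adjusted p up to 0.287), but not without nicotine ICM 1 or nicotine TE 1. Larp1 kept its call in 28 of 30 alternatives (limma adjusted p up to 0.287), but not without nicotine ICM 2. The count was 82 without control TE 1, 76 without control TE 2, 59 without nicotine ICM 1, 39 without nicotine ICM 2, 46 without nicotine TE 1, 49 without nicotine TE 2, 89 without control morula 1, 88 without control morula 2 and 95 without nicotine morula 2, against 153 (35 higher and 118 lower, but 22 and 88 without nicotine morula 1 and 23 and 92 without nicotine morula 3). Only the groups compared gave 3, array weights 5, removal of a length trend 83, of mitochondrially encoded genes 74 and of nicotine TE 2 and nicotine ICM 1 together 67, 54 passed at a pseudocount of 0.1 and 265 at 5, no filter gave 77 and the stricter filter 53, and higher and lower genes numbered 47 and 36 at the same sum (median of all genes 0.10), 38 and 45 after centring on the median (0.01), 22 and 23 after quantile normalization (0.01) and 39 and 47 without a GC trend (0.003).

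Averaged over the 3 stages, p53 targets and lysosome and autophagy genes were higher with nicotine as lists by camera (calls lost with an estimated correlation). The p53 targets that rose included the apoptosis genes Bbc3 and Pmaip1, the p53 inhibitor Mdm2 and the kinase Plk2. Bbc3 changed by 1.01 on the log2 scale (limma adjusted p = 0.0134), and Pmaip1 by 1.47 (limma adjusted p = 0.00847). Mdm2 changed by 0.75 (limma adjusted p = 0.0246). Plk2 changed by 1.75 (limma adjusted p = 0.00611). Apoe changed by 1.96 (limma adjusted p = 0.000424) and the cathepsin Ctsd by 0.66 (limma adjusted p = 0.0227). Of the Notch pathway 3 of 33 members rose. Hes1 rose by 0.80 (limma adjusted p = 0.0283) and Ncstn, a subunit of the gamma-secretase that cleaves Notch, by 0.60 (limma adjusted p = 0.0471). Dtx1, a ubiquitin ligase of the pathway, rose by 0.78 (limma adjusted p = 0.0102). All of these genes had fitted changes above 0 in each of the 3 stages. Apoe, Bbc3 and Dtx1 held without any 1 library. Hes1 kept its call in 21 of 29 alternatives (limma adjusted p up to 0.0967), but not without control ICM 1, control TE 1 or 2, nicotine ICM 2, nicotine TE 1, control morula 2 or nicotine morula 1. Ncstn kept its call in 9 of 29 alternatives (limma adjusted p up to 0.134), but not without control ICM 1 or 2, control TE 1 or 2, nicotine ICM 1 or 2, nicotine TE 1 or 2, control morula 2 or nicotine morula 1 or 3.

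The averaged comparison passed 476 genes by limma, 374 higher and 102 lower, with a median of 0.075 over all tested genes and 2388 at an unadjusted p under 0.05. By camera 8 lists passed and 0 with an estimated correlation (by fry, 4). Higher were p53 targets (0.58; camera adjusted p = 4.59e-13, or 0.357 with an estimated correlation; 14 of 28 higher, 23 when adjusted by list). Immediate early genes followed (0.51; camera adjusted p = 1.96e-06, or 0.366 with an estimated correlation; 4 of 14 higher, 10 when adjusted by list). Lysosome and autophagy genes passed as well (0.20; camera adjusted p = 1.01e-05, or 0.366 with an estimated correlation; 10 of 47 higher, 16 when adjusted by list). Junctions and cavity formation (0.24; camera adjusted p = 0.0224, or 0.543 with an estimated correlation; 4 of 31 higher, 9 when adjusted by list) passed too. So did the Notch pathway (0.15; camera adjusted p = 0.0224, or 0.58 with an estimated correlation; 6 when adjusted by list). Lower were ribosomal proteins (-0.23; camera adjusted p = 5.3e-11, or 0.45 with an estimated correlation), with 2 of 58 past the threshold (Rpl18a and Rpl30) and 2 when adjusted by list. Oxidative phosphorylation was lower (-0.25; camera adjusted p = 6.55e-09, or 0.428 with an estimated correlation), with 3 of 62 past the threshold (Ndufa5, Ndufa4 and Ndufa3) and 10 when adjusted by list. The erratic mitochondrially encoded genes were lower (-0.36; camera adjusted p = 0.0261, or 0.366 with an estimated correlation), with 0 of 13 past the threshold. Notch pathway genes did not pass without control ICM 1, nicotine ICM 2, nicotine TE 2 or control morula 2 (0.13 to 0.19). Junctions and cavity formation did not pass without control ICM 1, nicotine ICM 1, nicotine TE 2 or control morula 2 (0.11 to 0.20). Mitochondrially encoded genes did not pass without nicotine ICM 1 or 2, nicotine TE 2 or control morula 2 (-0.87 to -0.31) and moved to -0.82 without control TE 2 and -0.61 without nicotine TE 1. Ribosomal protein genes moved to -0.15 without control morula 2. The averaged count was 316 without control ICM 1, 269 without control ICM 2, 140 without control TE 1, 247 without control TE 2, 257 without nicotine ICM 1 or nicotine morula 1 and 186 without control morula 2, against 476 (374 higher and 102 lower, but 240 and 95 without nicotine TE 2 and 360 and 62 without control morula 1). No filter gave 180, a replicate block 230 and omission of nicotine TE 2 and nicotine ICM 1 together 270, and higher and lower genes numbered 220 and 163 after centring on the median, 268 and 204 after quantile normalization and 185 and 134 without a GC trend.

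Direct tests of whether the nicotine effect differed between stages passed 7 genes between TE-labelled and ICM-labelled libraries (2 higher and 5 lower in TE), 1 between ICM-labelled libraries and morulae (lower in ICM) and 13 between TE-labelled libraries and morulae (3 higher and 10 lower in TE). The unadjusted p was under 0.05 for 897, 1114 and 1377 genes. Larp1 differed between TE-labelled and ICM-labelled libraries by -5.67 on the log2 scale (limma adjusted p = 0.000489). It rose in ICM-labelled and fell in TE-labelled libraries, as swapped control labels would also give. Spic differed between TE-labelled libraries and morulae by -3.45 (limma adjusted p = 0.00216). The 3 genes with a higher effect in TE-labelled libraries than in morulae were Fas, Txn1 and the predicted gene Gm14325, which was named after its values were seen. Larp1 and Spic held these calls without any 1 library. The TE and ICM count was 25 without control ICM 1, 2 without control ICM 2 or nicotine morula 3, 4 without control TE 1, 3 without control TE 2 or nicotine ICM 2, 20 without nicotine TE 1, 14 without nicotine TE 2 and 1 without control morula 1 or 2 or nicotine morula 1 or 2, against 7. The TE and morula count was 4 without control TE 1 or control morula 2, 3 without control TE 2, 40 without nicotine TE 1, 6 without nicotine TE 2, 2 without nicotine morula 1 and 8 without nicotine morula 2, against 13 (3 higher and 10 lower, but 2 and 2 without control TE 1 and 6 and 8 without nicotine morula 3). The ICM and morula count of 1 (Ly6i, -2.86; limma adjusted p = 0.0178, lost without nicotine ICM 2, control morula 1 or 2 or nicotine morula 1 or 3) was 5 without control ICM 1, 3 without control ICM 2, 4 without nicotine ICM 1, 0 without nicotine ICM 2 or nicotine morula 1 or 3 and 2 without control morula 1; the limma counts of 0 stood beside 1183, 887 and 1253 genes at an unadjusted p under 0.05.

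Few genes were called in more than 1 stage. Apoe and Tspan17, a tetraspanin named after its values were seen, rose in both morulae and TE-labelled libraries, where 0.323 shared genes would occur if the calls were independent, and Xlr3a fell in both (0.141 if independent). Pramel5 fell in both ICM-labelled and TE-labelled libraries (0.004 if independent), and morulae and ICM-labelled libraries shared 0 limma calls (0.207 higher and 0.028 lower if independent). Across the 11386 tested genes, which are not independent replicates, the log2 changes correlated at r = 0.190 (rho = 0.193) between morulae and ICM-labelled libraries. The coefficients were r = 0.109 (rho = 0.0961) between morulae and TE-labelled libraries and r = 0.272 (rho = 0.278) between ICM-labelled and TE-labelled libraries. The first was 0.117 without control ICM 2 and 0.125 without nicotine morula 3. The second was 0.0329 without nicotine TE 1, 0.0468 without nicotine morula 3, 0.0606 without control morula 1 and 0.0693 without control TE 1.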

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

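The tests of scaling in TE-labelled libraries, of a higher share of trophectoderm cells, of swapped labels and of mixed samples were chosen only after the results were seen, as were the alternatives that remove a length trend, a GC trend or a pair of libraries that differ in sex-linked genes.

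The first pattern is the higher expression of p53 target genes with nicotine in TE-labelled libraries (1.04 on the log2 scale relative to all tested genes). Sex makeup as the whole cause is argued against by the list's median of 1.0966 without nicotine TE 2 and nicotine ICM 1 (1.0229 with all libraries). On the nicotine side this value rests on 1 library, nicotine TE 1. A factor common to all genes of a library is argued against by the median of all tested genes, within 0.0563 of 0 with all libraries or 1 TE-labelled library left out; a test fixed beforehand on medians relative to all genes was set aside, as such a factor hardly moves them. A higher share of trophectoderm cells in the nicotine libraries stays open: p53 targets lay at -0.2002 in TE-labelled relative to ICM-labelled control libraries, but trophectoderm markers did not part those libraries either (camera adjusted p = 0.718), a condition set after the value was seen, which would else have argued against this explanation. A response of p53 target genes to nicotine remains a hypothesis, the camera call is lost with an estimated correlation (adjusted p = 0.171), and differences of culture, RNA quality or instrument were not tested.

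The second pattern is the lower expression of ribosomal protein and oxidative phosphorylation genes with nicotine in morulae. Transcript length as the whole cause is argued against by medians of -0.5534 (-0.714 with the trend kept) and -0.3751 (-0.5341) after a length trend was removed, and GC content by medians of -0.7206 and -0.5558 after a GC trend was removed; random lists matched in length or GC content did not reach the medians of the real ones. A single library as the cause is argued against by medians from -0.9219 to -0.5003 and from -0.729 to -0.4572 with 1 morula library left out. Both calls are lost with an estimated correlation (adjusted p = 0.203 and 0.246). RNA quality, expression level, genes detected and developmental timing were not tested. All 13 mitochondrially encoded genes also had lower fitted means (list median -0.59, camera adjusted p = 0.061, from a variance shared with the erratic stages). An effect of nicotine on these mRNAs is thus only a hypothesis.

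The third pattern is that lineage markers did not part the control ICM-labelled and TE-labelled libraries. Scaling, swapped labels and mixed samples stay open. For scaling, an adjusted p of at least 0.226 under 3 other scalings decides nothing, since these moved both lists by at most 0.0611. For the others, list medians of -0.1008 for trophectoderm and -0.1407 for epiblast markers (ICM minus TE) restate the pattern. So do ratios of means of 0.978 for Krt8, 1.03 for Krt18 and 0.7275 for Cldn4. Larp1 and Nanog (222 and 327 FPKM in control ICM and TE, 286 and 184 with nicotine) reversed, as swapped control labels would give. Mean Sox2 and Pou5f1 did too, with overlapping libraries. Cdx2 (2.48 and 3.92, then 4.14 and 7.90) and Gata3 did not. All 3 causes were set aside after the values were seen. The labels give no dissection or sorting method, and incomplete parting at collection was not tested.

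What sets the following results apart is a test of the difference between stages itself, with 2 or 3 libraries per group. The difference in nicotine effect between TE-labelled and ICM-labelled libraries (the TE effect minus the ICM effect, log2) passed in limma for Canx (-2.271, adjusted p = 0.0494), Gadd45g (3.429, adjusted p = 0.0494), Larp1 (-5.671, adjusted p = 0.000489), Siah1b (-2.513, adjusted p = 0.0494), Eif1a (-1.921, adjusted p = 0.0455), mt-Cytb (9.871, adjusted p = 0.0282) and Snord52 (-3.246, adjusted p = 0.0282). Without 1 library, only Larp1 held its call throughout. By camera these lists differed relative to all genes, but none with an estimated correlation. Trophectoderm markers differed by 0.557 (adjusted p = 0.0112, or 0.682 with an estimated correlation) and epiblast and inner cell mass markers by -0.33 (adjusted p = 0.0402, or 0.54 with an estimated correlation). The p53 targets differed by 0.671 (adjusted p = 1.39e-07, or 0.371 with an estimated correlation) and mitochondrially encoded genes by 0.63 (adjusted p = 0.0361, or 0.371 with an estimated correlation). Cell cycle genes of S and G2/M phase differed by -0.449 (adjusted p = 0.000417, or 0.371 with an estimated correlation) and immediate early genes by 0.533 (adjusted p = 0.000757, or 0.495 with an estimated correlation). Mitochondrial values are erratic between replicates here. Epiblast markers did not pass without control ICM 2, control TE 1, nicotine ICM 2 or nicotine TE 1 (-0.25 to -0.11) and moved to -0.56 without control ICM 1. The p53 targets moved to 0.38 without control ICM 1. Trophectoderm markers did not pass without control ICM 2, nicotine ICM 2 or nicotine TE 2 (0.36 to 0.43). Mitochondrially encoded genes did not pass without control ICM 2, control TE 2, nicotine ICM 1 or 2 or nicotine TE 1 (0.09 to 1.98) and moved to 2.03 without control TE 1 and 0.18 without nicotine TE 2. Cell cycle genes moved to -0.30 without control ICM 2 and -0.23 without nicotine TE 2. Immediate early genes did not pass without nicotine TE 1 (0.41) and moved to 0.89 without nicotine TE 2.

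For the difference between ICM-labelled libraries and morulae (the ICM effect minus the morula effect, log2), limma passed Ly6i (-2.864, adjusted p = 0.0178). Ly6i lost its call without nicotine ICM 2, control morula 1 or 2 or nicotine morula 1 or 3. These lists differed by camera relative to all genes, but none with an estimated correlation. Integrated stress and unfolded protein response differed by -0.326 (adjusted p = 0.00392, or 0.621 with an estimated correlation) and heat shock proteins by 0.511 (adjusted p = 0.00193, or 0.202 with an estimated correlation). Nuclear-encoded oxidative phosphorylation differed by 0.392 (adjusted p = 3.7e-08, or 0.52 with an estimated correlation) and cytosolic ribosomal proteins by 0.658 (adjusted p = 1.09e-23, or 0.273 with an estimated correlation). Cell cycle genes of S and G2/M phase differed by 0.286 (adjusted p = 0.0124, or 0.52 with an estimated correlation) and early 2-cell stage genes by -0.646 (adjusted p = 0.00972, or 0.202 with an estimated correlation). Cell cycle genes did not pass without control ICM 2 (0.15) and moved to 0.47 without control ICM 1. Early 2-cell stage genes did not pass without control ICM 1 or control morula 1 (-0.75 to -0.50). The stress response list did not pass without nicotine ICM 1 or control morula 1 (-0.28 to -0.26) and moved to -0.62 without nicotine ICM 2 and -0.55 without control morula 2. Oxidative phosphorylation moved to 0.24 without control morula 2. Ribosomal protein genes moved to 0.41 without control morula 2.

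In the difference between TE-labelled libraries and morulae (the TE effect minus the morula effect, log2), limma passed Spic (-3.447, adjusted p = 0.00216), Canx (-2.102, adjusted p = 0.0425), Ly6i (-2.618, adjusted p = 0.0166), Fas (2.465, adjusted p = 0.0425), Txn1 (1.488, adjusted p = 0.0452), Ccpg1 (-2.057, adjusted p = 0.0461), Larp1 (-3.015, adjusted p = 0.0425), Siah1b (-2.653, adjusted p = 0.0295) and Eif1a (-2.596, adjusted p = 0.00216). Only Eif1a and Spic held theirs without any 1 library. Camera passed these lists relative to all genes, but none with an estimated correlation. Trophectoderm markers differed by 0.275 (adjusted p = 0.0191, or 0.627 with an estimated correlation) and epiblast and inner cell mass markers by -0.495 (adjusted p = 0.0245, or 0.465 with an estimated correlation). The p53 targets differed by 0.448 (adjusted p = 0.00175, or 0.52 with an estimated correlation) and oxidative stress and glutathione by 0.296 (adjusted p = 0.00175, or 0.465 with an estimated correlation). Integrated stress and unfolded protein response differed by -0.29 (adjusted p = 0.00175, or 0.465 with an estimated correlation) and lysosome and autophagy by -0.232 (adjusted p = 0.0273, or 0.627 with an estimated correlation). Nuclear-encoded oxidative phosphorylation differed by 0.542 (adjusted p = 4.92e-08, or 0.465 with an estimated correlation) and cytosolic ribosomal proteins by 0.808 (adjusted p = 6.06e-29, or 0.314 with an estimated correlation). Early 2-cell stage genes differed by -0.78 (adjusted p = 0.0192, or 0.314 with an estimated correlation). Eif1a is the member of the early 2-cell stage list past the threshold here, and Canx that of the stress response list. Trophectoderm markers did not pass without nicotine TE 2 or control morula 1 (0.31 to 0.32) and moved to 0.43 without control TE 1, 0.67 without nicotine TE 1 and 0.43 without nicotine morula 3. Epiblast markers did not pass without control TE 1, nicotine TE 1, control morula 1 or nicotine morula 2 (-0.51 to -0.28). The p53 targets did not pass without control TE 1 or nicotine TE 1 (0.35 to 0.37) and moved to 0.29 without nicotine morula 1. Lysosome and autophagy did not pass without control TE 2, nicotine TE 2, control morula 1 or nicotine morula 3 (-0.27 to -0.08). Early 2-cell stage genes did not pass without nicotine TE 2 or control morula 1 (-0.76 to -0.45) and moved to -0.39 without nicotine morula 2. Oxidative stress genes moved to 0.52 without control morula 1 and 0.15 without control morula 2. The stress response list did not pass without control morula 1 (-0.16) and moved to -0.54 without control morula 2.

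Outlying libraries were probed only by array weights and by leaving each out, and the table has no columns per library other than FPKM.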

How the results depend on the processing

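The alternatives without mitochondrially encoded genes, without genes that jump from 0, without a pair of libraries, without a length trend and without a GC trend were chosen after the data were seen. No named gene past the threshold reversed direction, and the lists called in a comparison kept the sign of their median relative to all genes with 1 library left out. Under the alternatives fixed beforehand, values of named genes past the threshold kept their call in 1065 of 1718 for morulae, 249 of 370 for ICM-labelled libraries, 495 of 669 for TE-labelled libraries, 1866 of 2382 for the average, 184 of 274 for ICM against TE in controls, 573 of 918 for ICM against TE with nicotine, 75 of 173 for TE minus ICM, 16 of 24 for ICM minus morula and 136 of 223 for TE minus morula, and the others were weaker. Named genes not past it gained a call in 38 of 2547 for morulae, 50 of 3405 for ICM-labelled libraries, 38 of 2981 for TE-labelled libraries and 25 of 3410 for ICM against TE in controls. Under those added later, calls were kept in 274 of 345 for morulae, 60 of 75 for ICM-labelled libraries, 109 of 134 for TE-labelled libraries, 407 of 500 for the average, 37 of 55 for ICM against TE in controls, 117 of 184 for ICM against TE with nicotine, 18 of 34 for TE minus ICM, 5 of 5 for ICM minus morula and 38 of 45 for TE minus morula. Apoe, Ly6a, Canx and Eif1a in TE-labelled libraries kept their call under all 30 alternatives, with log2 changes of Apoe from 2.17 to 2.67. Counts of genes were far less stable: those more than 1.5 times above or below the value with all libraries follow, each against the count in the report.

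With a pseudocount of 0.1 the counts were 4 for ICM-labelled libraries, 8 for ICM lists, 10 for TE-labelled libraries, 54 for ICM against TE with nicotine, 1 for TE minus ICM and 0 for ICM minus morula. With a pseudocount of 5 the counts were 104 for ICM-labelled libraries, 99 for TE-labelled libraries, 265 for ICM against TE with nicotine and 26 for TE minus morula. Without a filter the counts were 23 for morulae, 99 for ICM-labelled libraries, 180 for the average, 73 for ICM against TE in controls, 77 for ICM against TE with nicotine, 34 for TE minus ICM, 11 for ICM minus morula and 2 for TE minus morula. With the stricter filter the counts were 10 for ICM-labelled libraries, 24 for TE-labelled libraries, 53 for ICM against TE with nicotine and 0 for ICM minus morula. Scaling to the same sum gave 41 for ICM-labelled libraries, 7 for ICM against TE in controls, 83 for ICM against TE with nicotine and 12 for TE minus ICM. After centring on the median the counts were 6 for ICM against TE in controls, 83 for ICM against TE with nicotine and 4 for TE minus ICM. After quantile normalization the counts were 104 for morulae, 30 for ICM-labelled libraries, 1 for ICM lists, 7 for ICM against TE in controls, 45 for ICM against TE with nicotine and 2 for TE minus ICM. With only the groups compared the counts were 0 for morulae, 1 for ICM-labelled libraries, 6 for TE-labelled libraries, 2 for ICM against TE in controls, 3 for ICM against TE with nicotine, 2 for TE minus ICM and 0 for ICM minus morula. Without the intensity trend the counts were 32 for morulae, 3 for TE minus ICM and 4 for TE minus morula. With robust empirical Bayes the counts were 36 for ICM-labelled libraries and 11 for TE minus ICM. With array weights the counts were 396 for morulae, 11 for ICM-labelled libraries, 90 for ICM against TE in controls, 5 for ICM against TE with nicotine and 20 for TE minus morula. With a replicate block the counts were 23 for morulae, 4 for ICM-labelled libraries, 5 for ICM lists, 13 for TE-labelled libraries, 230 for the average, 2 for TE minus ICM, 0 for ICM minus morula and 2 for TE minus morula. Without mitochondrially encoded genes the counts were 74 for ICM against TE with nicotine and 2 for TE minus ICM. Without genes that jump from 0 between replicates the counts were 1 for ICM lists and 11 for TE minus ICM. Without nicotine TE 2 and nicotine ICM 1 together the counts were 1 for ICM lists, 270 for the average, 22 for ICM against TE in controls, 67 for ICM against TE with nicotine, 18 for TE minus ICM, 6 for ICM minus morula and 8 for TE minus morula. Without a length trend the counts were 109 for morulae, 0 for ICM lists, 5 for ICM against TE in controls, 83 for ICM against TE with nicotine and 2 for TE minus ICM. Without a GC trend the counts were 1 for ICM lists, 23 for TE-labelled libraries, 4 for ICM against TE in controls, 86 for ICM against TE with nicotine and 4 for TE minus ICM. Camera with an estimated correlation gave 0 lists in morulae, ICM-labelled and TE-labelled libraries. With fry in place of camera the counts were 0 for ICM lists and 1 for TE lists. Where limma gave 0 genes for ICM minus morula, 1083, 686, 1073 and 1039 genes had an unadjusted p under 0.05 (with a pseudocount of 0.1, with the stricter filter, with only the groups compared and with a replicate block). With 1 library left out the counts ranged from 12 to 278 for morulae, 5 to 8 for morula lists, 2 to 56 for ICM-labelled libraries, 0 to 6 for ICM lists, 9 to 64 for TE-labelled libraries, 2 to 9 for TE lists, 140 to 613 for the average, 1 to 22 for ICM against TE in controls, 39 to 160 for ICM against TE with nicotine, 1 to 25 for TE minus ICM, 0 to 5 for ICM minus morula and 2 to 40 for TE minus morula. Fewer libraries or more tested genes account for part of these moves by construction; for all others the cause was not tested. The replicate block assumes pairs that the values do not bear out, since deviations of equally numbered libraries correlated at -0.174 to 0.021. For the averaged contrast, only the groups compared is the same fit and gave no further value. Depth is unknown, so no counting error could be set against any value.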

Other observations

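No test in this part was chosen only after its result was seen. Averaged over the 3 stages, 5 of 34 genes of the stress response list fell and 2 rose. Manf, a factor secreted under endoplasmic reticulum stress, fell by 1.50 on the log2 scale (limma adjusted p = 0.00305). Hsp90b1 fell by 1.18 (limma adjusted p = 0.0133), and the chaperone Hspa5 by 1.10 (limma adjusted p = 0.0212). Canx fell by 0.93 (limma adjusted p = 0.00625) and the disulfide isomerase Pdia6 by 0.89 (limma adjusted p = 0.00678); fitted changes of Canx were -0.28 in morulae, -0.11 in ICM-labelled and -2.38 in TE-labelled libraries. Slc3a2 rose by 0.68 (limma adjusted p = 0.00847), and so did Sesn2, a stress-induced inhibitor of growth signalling, by 0.79 (limma adjusted p = 0.0471). With 27 not past the threshold, the list as a whole did not pass (0.03; camera adjusted p = 0.587).

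Of 23 genes of the glycolysis list 3 had a higher average and 1, Egln3, a lower one (-0.55; limma adjusted p = 0.049): the higher ones were Tpi1 (1.18; limma adjusted p = 0.0202), Pkm (0.71; limma adjusted p = 0.00794) and Eno1 (0.66; limma adjusted p = 0.0365). Of 32 of cholesterol synthesis, Srebf2 (0.79; limma adjusted p = 0.0366), Acat2 (0.65; limma adjusted p = 0.0267) and Dhcr7 (0.93; limma adjusted p = 0.0399) rose; the fitted change of Srebf2 in TE-labelled libraries was -0.21. Of 33 DNA damage repair genes, H2afx (1.52; limma adjusted p = 0.00305) and Xrcc1 (0.96; limma adjusted p = 0.0133) rose as well. None of these lists passed by camera as a whole (adjusted p = 0.078 for glycolysis, 0.132 for cholesterol and fatty acid synthesis and 0.743 for DNA damage repair).

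Regrouping the libraries within stages tested whether chance could give the averaged count of 476 genes. Of 100 regroupings drawn from 360 possible ones, the real one included, 1 gave as many genes, the real one; the highest of the others gave 57 genes. If libraries are independent, chance is unlikely here, but a difference of culture or handling stays open.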
